A study of Mus musculus with 6 samples.

How the data were processed

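Poly-T purified mRNA from 6 primary bone marrow cultures was sequenced after preparation with a NEBNext Ultra kit from 3 µg of RNA, per the labels' protocols. The values are FPKM as deposited by the authors, in a table with a column for each library. HTSeq 0.6.0 and DESeq2 1.10.1 are named in the submitters' processing notes, with no role given. The aligner, genome build, annotation and strand setting are not given in the sources used here. Replicates are biological per the series' design text, but which mice or litters they came from is not stated there.

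The table held 23622 genes with Ensembl identifiers, of which 195 were at 0 in all libraries. Symbols, coordinates, exons and GC content came from GENCODE vM21 (GRCm38), in which 99.5% of the identifiers were found, while 112 had no symbol. The lengths behind the FPKM equalled the exon unions of that annotation for 78.1% of 23315 genes, and that of Ift140 was 7572 against 8333 bases. Low FPKM values of a gene are whole multiples of what 1 read is worth, and whole reads were recovered for 23425 of 23427 genes with a value (99.99%, within a tolerance of 1e-06). The recovered reads summed to 16010533 to 27897940 per library. The library total behind the FPKM was 1.65 times as large in the deepest library as in the shallowest. Floors of 3 reads per library cover counting error only.

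Groups were taken from the genotype labels, 3 libraries each. FPKM was transformed as log2(FPKM + 1), and the 13326 genes with a mean of at least 0.5 FPKM were tested with limma 3.58.1 in R 4.3.3. The test was limma's moderated test with an intensity trend, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, and no covariate. Adjusted p values in the text come from limma, or from limma's camera where a list is tested. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 34 of 38 lists with at least 5 measured members, and again with an estimated correlation and with fry. Ranges over alternative fits hold up to 22 refits. Reads were recovered and tables made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9.

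The test, the lists and the rule for named genes were fixed before the data were examined, as were most alternatives. That rule took Ift140 and then genes past the threshold, with at least 1 FPKM in the higher group and no overlap between groups, namely the 12 largest rises and 12 largest falls, leaving out clone-type names and pseudogenes. From each list it took up to 4 members that passed, by size of change, or the 2 with the smallest unadjusted p where none passed. Of the genes so taken 3 are not reported here by name. The lists held IFT-A, IFT-B and motor, BBSome and ciliary membrane, Hedgehog, osteoblast and osteocyte, adipocyte, insulin and IGF, secreted factor, Wnt, TGF-beta and BMP, matrix, protease, proliferation, senescence and p53, stromal progenitor and chondrocyte genes. They also held smooth muscle, skeletal muscle, macrophage, osteoclast, granulocyte, lymphocyte, erythroid, endothelial, neural, interferon, inflammatory, complement and immediate early genes. The others were glycolysis, oxidative phosphorylation, cholesterol and fatty acid synthesis, unfolded protein response, hypoxia, NRF2, mitochondrially encoded, ribosomal protein and sex-linked genes. The names Wisp1 and Wisp2 were updated to Ccn4 and Ccn5.

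The alternatives were other pseudocounts, filters, scalings, variance priors, library weights, a replicate block, leaving out each library in turn, another threshold and a minimum fold. Those chosen after seeing the data were voom on the recovered reads, a correction of each library for its trend with GC content (loess, span 0.5), that correction with the replicate block, leaving out genes on X and Y, and protein-coding genes with more than 1 exon.

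The procedure was tested on simulated reads drawn from the means and totals of these libraries, with independent genes, 13334 of them tested. Every gene was given the same dispersion of 0.00477, so differences in spread between genes or between libraries were not simulated. Recovery in the real data can therefore be lower, and false calls more frequent, than given here. Of 50 genes changed at each fold, it recovered 8% at 1.25-fold, 56% at 1.5-fold, 84% at 2-fold and 94% at 4-fold, and 11 unchanged genes were called beside them. With voom on the same simulated reads the shares were 32%, 78%, 90% and 94%. With no gene changed 0 genes and 0 lists were called. A slope with GC content alone gave 1346 calls, and 0 after the GC correction. That slope was linear, equal in all cKO libraries and set on the GC values used to correct it. Its removal therefore tests the procedure, not whether the correction suits the real trends, which differed between libraries. Read recovery was tested on 2892 simulated genes and returned 100.0% of them, up to a factor shared by all values of a gene. The steps that set this factor and the library totals were not part of that test.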

Results

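Ift140 is a subunit of the intraflagellar transport A (IFT-A) complex, which carries cargo back from the tip of the primary cilium. Messenger RNA was profiled in 6 cultures of bone progenitors grown from the marrow of C57BL/6 mice aged 2 weeks and taken to culture generation 3, untreated. The labels put 3 cultures in a wild-type control group and 3 in a group labelled Ift140-/- (cko), called cKO here, and the series describes the samples of each group as biological replicates. They carry the numbers 2, 3 and 4 in each group. The series concerns Ift140 of osteoblasts and insulin sensitivity, so the comparison asks which genes differ in marrow progenitors that carry the deletion. The deposited values are FPKM, read numbers scaled by gene length and by the library's total. The library totals that lie behind them were 20158329, 21581625 and 20770169 reads in controls 2, 3 and 4, and 17180101, 18044678 and 28283414 reads in cKO 2, 3 and 4. Between 19874 and 20686 of the 23622 genes had a value above 0 in each library, and 13326 with a mean FPKM of at least 0.5 were tested.

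Ift140 was lower in all 3 cKO libraries but not absent. Its level was 2.97 ± 0.194 FPKM in controls and 1.79 ± 0.0951 FPKM in cKO (SD, n = 3 each), so 60.2% of the control level remained, and the groups did not overlap. The control libraries 2, 3 and 4 had 3.11, 2.75 and 3.05 FPKM, from 475, 449 and 479 reads. The cKO libraries had 1.72, 1.74 and 1.90 FPKM, from 224, 238 and 406 reads. The gene (ENSMUSG00000024169) lies on chromosome 17 from 25016085 to 25099495 on the plus strand of GRCm38, with up to 30 exons in a GENCODE vM21 transcript, and Tmem204 is nested in it on the other strand. A gene-wide FPKM does not show which exons the deletion removed. The log2 fold change on the log2(FPKM + 1) scale was -0.51 (SE 0.07, limma adjusted p = 0.0138, 0.00294 to 0.0724 over 22 alternative fits). The 2-sided exact permutation p was 0.1, the smallest that 3 against 3 can give. Without control replicate 4 and without cKO replicate 3 the adjusted p was 0.0721 and 0.0599, with log2 fold changes of -0.49 and -0.50.

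Genes that mark sex separated the groups completely. Xist, the RNA that silences the second X chromosome of female cells, was at 0.0732 ± 0.0401 FPKM in controls and 38.2 ± 1.85 FPKM in cKO (SD, n = 3), a 522-fold difference. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 5107, 3509, 1807 and 1210 reads over the 3 controls. Over the 3 cKO libraries Ddx3y had 1 read and the other 3 had 0. Against a floor of 3 reads per library, Eif2s3y was at least 376.2-fold, Kdm5d at least 193.9-fold and Uty at least 129.8-fold higher in controls, which covers counting error only. X-linked genes that are known to escape silencing, Kdm5c (19.5 ± 1.08 to 29.7 ± 2.22 FPKM), Eif2s3x (19.1 ± 1.54 to 28.3 ± 0.387), Kdm6a and Pbdc1, were also higher in cKO, with limma adjusted p of 0.0120, 0.0120, 0.0150 and 0.0173. Ddx3x did not pass (52.2 ± 2.67 and 56.4 ± 1.31 FPKM, adjusted p = 0.271). These genes were chosen after their values were seen. The 3 controls thus carried a male and the 3 cKO libraries a female expression pattern. The labels used here name no sex, and each genotype comparison that follows is also a comparison of these patterns. Of the 5 genes of the sex-linked list 1 rose and 4 fell, over all genes and adjusted over the list alone (camera adjusted p = 3.04e-04, 1.01e-05 to 0.00135 over the 19 fits that held the list). That adjusted p was 0.504 with an estimated correlation.

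**Figure D1:**
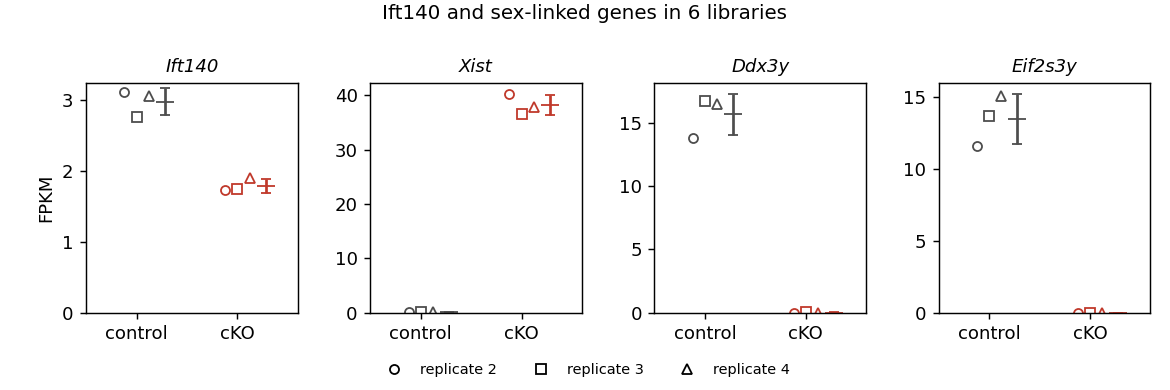
FPKM of Ift140, Xist, Ddx3y and Eif2s3y in each library (linear axes from 0, open symbols by replicate number), with the mean and SD of each group of 3 beside the points. Ift140 lay at 2.75 to 3.11 FPKM in controls and 1.72 to 1.90 FPKM in cKO, whereas Xist was found in the cKO libraries and the Y-linked genes in the controls.

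Between the groups 672 genes were higher and 342 lower in cKO (limma, Benjamini-Hochberg adjusted p under 0.05), 7.6% of those tested. Fold changes from this test are on the log2(FPKM + 1) scale, which understates the change of low genes. Outside Xist, the largest rises were in Klf2, a transcription factor of quiescent cells and of vessel lining, Frat1, which stabilises beta-catenin, the deubiquitinase Otud1, the retinol carrier Rbp4, the cystatin Stfa3, Ism1, Igf2, the osteocalcin gene Bglap2, the matrix proteoglycan gene Omd (osteomodulin), the ligand Wnt11 and Gdf10. Klf2 rose from 128 ± 57.4 to 524 ± 90.2 FPKM (SD, n = 3; 4.10-fold, log2 fold change 2.13, SE 0.35, adjusted p = 0.0218). Otud1 rose from 7.19 ± 2.65 to 26.4 ± 5.09 FPKM. Rbp4 rose 4.10-fold (log2 fold change 1.75, SE 0.28) and Ism1 went from 11.4 ± 2.69 to 39.4 ± 7.65 FPKM. Igf2, a growth factor that signals through the IGF1 and insulin receptors, went from 31.3 ± 12.6 to 102 ± 33.3 FPKM (3.25-fold). Omd went from 9.11 ± 3.54 to 30.2 ± 7.01, Wnt11 from 2.38 ± 0.408 to 9.62 ± 1.83, Frat1 from 1.82 ± 1.18 to 8.70 ± 3.42 and Gdf10 from 0.577 ± 0.431 to 3.89 ± 1.35 FPKM. Stfa3, which has close paralogs that can share its reads, went from 0.273 ± 0.0763 to 3.61 ± 2.54 FPKM. Its levels rested on 3, 2 and 2 reads in controls 2, 3 and 4 and on 46, 13 and 30 reads in cKO 2, 3 and 4. The call of Frat1 did not hold after a correction for GC content that was chosen after seeing the data, although its log2 fold change was 1.82 before and 1.59 after.

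Beyond the Y-linked genes, the largest falls were in C1qtnf3, a secreted C1q and TNF relative, Cemip, which breaks down hyaluronan, Cthrc1, a secreted protein of matrix-forming cells, the chemokine Ccl7, Ankrd1, a target of YAP, and Postn (periostin, a matrix protein of the periosteum). C1qtnf3 fell from 8.05 ± 2.67 to 1.77 ± 0.524 FPKM (log2 fold change -1.68, SE 0.24, adjusted p = 0.0148). Cemip fell from 43.3 ± 4.89 to 14.6 ± 0.898 (adjusted p = 0.00151), Cthrc1 from 35.8 ± 4.89 to 12.4 ± 0.560 (adjusted p = 0.00315) and Postn from 88.4 ± 13.0 to 37.6 ± 1.68 FPKM (adjusted p = 0.00541). Ccl7 went from 25.6 ± 9.75 to 9.07 ± 1.15 FPKM. Ankrd1 fell with a log2 fold change of -1.29 (SE 0.17). The rule for named genes also took Mir190a (2.88 ± 0.763 to 0.352 ± 0.609 FPKM) and Rnu73b (4.94 ± 1.33 to 1.40 ± 0.351), short RNA genes that lie within Tln2 and Rps3a1, with which they can share reads. These levels rested on 2 to 9 reads per library, or on none in 2 cKO libraries for Mir190a, and with voom on those reads neither passed (limma adjusted p = 0.0668 and 0.0730, over all refits 0.00495 to 0.12 for Mir190a and 0.00399 to 0.0816 for Rnu73b). After the GC correction the calls of Ccl7 and Mir190a did not hold, with log2 fold changes of -1.33 and -1.59 before and -1.26 and -1.51 after.

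The number of calls rested on which libraries were in the fit. It was 672 higher and 342 lower with all 6, but 45 and 26 without control replicate 4, 129 and 46 without cKO replicate 3, 282 and 101 without cKO replicate 2, and 308 and 136 without cKO replicate 4. Without control replicates 2 and 3 it was 589 and 253, and 626 and 374. Of the 93 genes that passed and were taken by the rule for named genes, other than Ift140, 18 kept their call without control replicate 4, 30 without cKO replicate 3 and 17 whichever library was left out, and none turned its direction in 22 alternative fits. Those 17 are the 5 sex-linked genes with Wnt11, Cemip, Cthrc1, Postn, Cebpa, Adipoq, Igfbp4, Ccn4, Fzd1, Id4, Adamts12 and Synpo2. Of the calls 66.3% were rises, against 52.1% after quantile normalization. After the GC correction 388 genes were higher and 344 lower. In all 1014 called genes the 3 values of each group did not overlap, as in 35.7% of all tested genes, where chance gives 10%. Without overlap, leaving out a library could not turn the direction of a called gene, so the kept directions are no support.

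**Figure D2:**
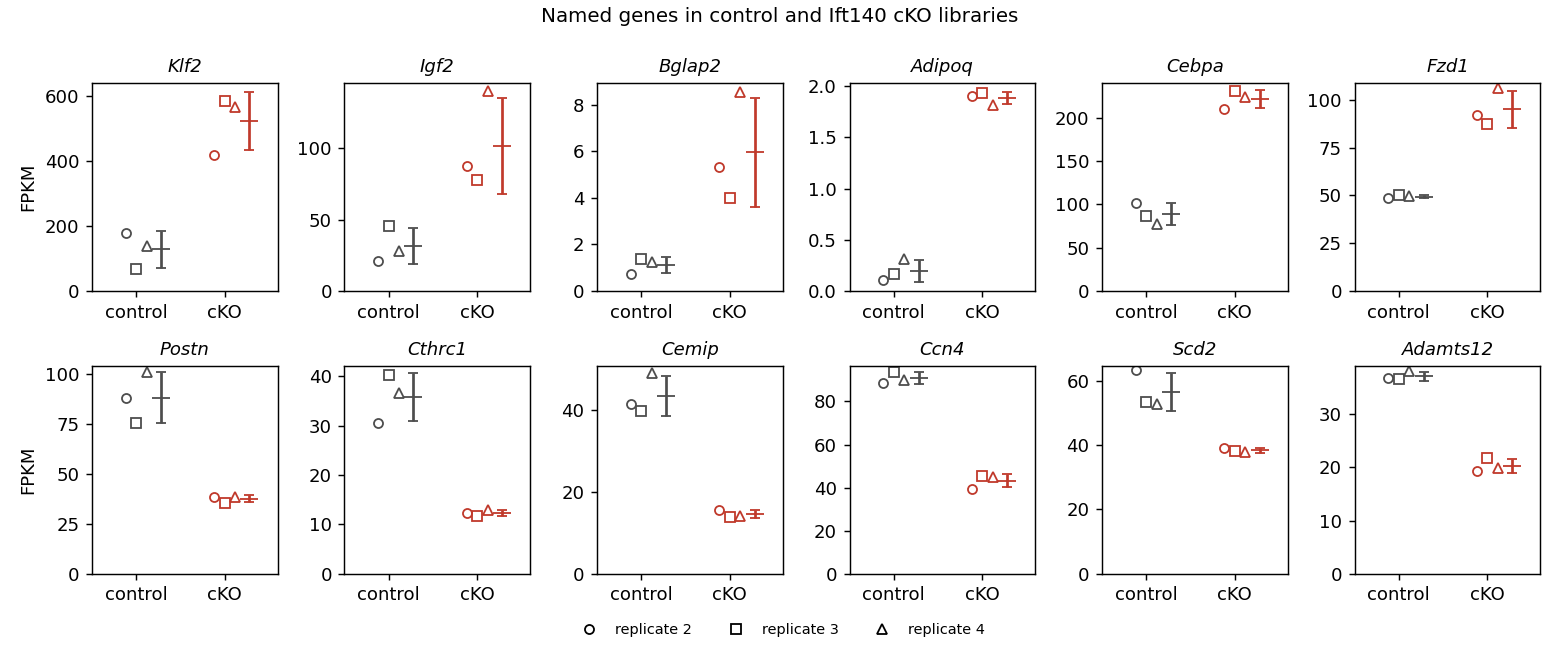
FPKM of 6 genes that rose and 6 that fell, in each library (linear axes from 0, open symbols by replicate number), with the mean and SD of each group of 3 beside the points. In each panel the 3 cKO values lie on one side of the 3 control values, for example 37.6 ± 1.68 against 88.4 ± 13.0 FPKM for Postn.

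Gene groups fixed before the data were examined were tested with camera, which asks whether a list moved relative to the other genes and takes an inter-gene correlation of 0.01 as given. Of the 34 lists with at least 5 measured members 6 were called higher and 8 lower at an adjusted p under 0.05. With the correlation estimated from these libraries none was (0 lists at an unadjusted p under 0.05; lowest adjusted p = 0.504), and fry, which tests a list by itself, called 4. These were the sex-linked list (adjusted p = 0.00106), the secreted factors (higher, 0.00106), IFT-A (lower, 0.00801) and the adipocyte list (higher, 0.00963). The IFT-A list holds the deleted gene Ift140, its only member past the threshold, and was not tested without it. Other divisions of the 6 libraries into 3 and 3 called up to 13 lists. For each list that camera called, the adjusted p is therefore followed by its range over alternative fits and by its value with an estimated correlation.

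Among the ciliary genes Ift140 was lower and the dynein-2 gene Wdr34 higher. None of the other 6 IFT-A members passed. Of those, named after their values were seen, Ift122 was at 1.78 ± 0.162 and 1.84 ± 0.152 FPKM in controls and cKO, Ttc21b at 1.97 ± 0.134 and 1.93 ± 0.0929, Wdr19 at 1.31 ± 0.0921 and 1.26 ± 0.0669 and Wdr35 at 2.59 ± 0.113 and 2.22 ± 0.128. Of the 7 members 1 fell, and 1 adjusted over the list alone (camera adjusted p = 0.183, fry 0.00801). As Ift140 is that member, the fry result does not show a fall of the rest of the complex. In the list of IFT-B and motor genes 1 of 26 rose, over all genes and adjusted over the list alone. This was Wdr34, an intermediate chain, from 6.11 ± 0.139 to 7.93 ± 0.487 FPKM (list adjusted p = 0.241). Its call did not hold after the GC correction, with log2 fold changes of 0.33 before and 0.14 after. Of 31 BBSome and ciliary membrane genes none passed by limma or, adjusted over the list alone, by the same test (3 at an unadjusted p under 0.05, 0 called by voom; adjusted p = 0.789), and their median and mean log2 fold changes were -0.01 and 0.02. Adcy3, an adenylyl cyclase of neuronal and other cilia, was at 11.2 ± 0.957 and 13.6 ± 1.24 FPKM and Nphp4 at 1.05 ± 0.0635 and 1.42 ± 0.202.

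Hedgehog signalling, which runs through the cilium, held 3 rises and no fall among 12 measured members (6 and 1 adjusted over the list alone). Smo, the pathway's transducer, rose from 42.7 ± 1.37 to 65.0 ± 6.14 FPKM (1.52-fold), the co-receptor Gas1 from 13.1 ± 3.44 to 27.5 ± 4.24 (2.09-fold) and the target Foxc2 from 23.3 ± 3.76 to 37.8 ± 1.49. Ptch1, a direct target, was at 5.16 ± 0.509 and 4.87 ± 0.782 FPKM and did not pass (adjusted p = 0.700; named after its values were seen). As a list these genes were higher (median log2 fold change 0.27, adjusted p = 0.0209, 0.00695 to 0.106 over 22 alternative fits, and adjusted p = 0.504 with an estimated correlation). The list did not pass in 4 of these fits, among them those without cKO replicate 4 (adjusted p = 0.0609), after the GC correction (0.0549), under which Foxc2 also lost its call (log2 fold change 0.69 before, 0.39 after), and among protein-coding genes with more than 1 exon (0.106).

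Osteoblast genes moved in both directions. Of 19 measured osteoblast and osteocyte genes 4 rose and 1 fell (6 and 3 adjusted over the list alone), and the list was not called (adjusted p = 0.201; 0.0438 without control replicate 3). Bglap2 rose from 1.11 ± 0.335 to 5.96 ± 2.35 FPKM and its neighbour Bglap from 0.848 ± 0.504 to 3.06 ± 0.787. These near-identical osteocalcin genes can share reads, so the split between them is uncertain, and Bglap did not pass after the GC correction (log2 fold change 1.16 before, 1.06 after). Omd rose and Postn fell as given above. Control replicate 3 stood apart from the other controls, at -20.4 on the second principal component against 15.4 and 11.4 for controls 2 and 4. Ibsp and Sp7, picked like Runx2 and Col1a1 after their values were seen, were highest there. The bone sialoprotein gene Ibsp was at 13.2, 92.4 and 20.1 FPKM in controls 2, 3 and 4 and at 41.9, 45.3 and 75.4 in the cKO libraries. The osteoblast factor Sp7 was at 28.8, 77.2 and 40.4 against 57.8, 45.4 and 69.2. Runx2 was at 8.29 ± 0.790 and 9.79 ± 1.35 FPKM (adjusted p = 0.250) and Col1a1 at 3029 ± 140 and 2623 ± 600 (adjusted p = 0.388).

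Adipocyte genes held 4 rises and 2 falls among 17 (7 and 2 adjusted over the list alone). The adipokine gene Adipoq rose from 0.196 ± 0.106 to 1.88 ± 0.0561 FPKM (adjusted p = 0.00349), the transcription factor genes Cebpa with a log2 fold change of 1.32 (SE 0.11, adjusted p = 0.00504) and Cebpb from 57.1 ± 18.4 to 138 ± 27.1 FPKM. Lpl, the lipoprotein lipase gene, rose 1.40-fold (log2 fold change 0.49, SE 0.11). Macrophage and granulocyte genes were also expressed in these cultures. Which cells gave these rises was not tested. The call of Cebpb, a gene of 67.2% GC, did not hold after the GC correction (log2 fold change 1.29 before, 0.82 after). Pparg was at 16.0 ± 0.935 and 16.2 ± 2.09 FPKM (adjusted p = 0.936; named after its values were seen), and the falls, in Scd1 and Acaca, belong to lipid synthesis. The list lay at the threshold (median log2 fold change 0.22, adjusted p = 0.0503, 0.00695 to 0.251 over 22 alternative fits). It was under the threshold in 7 of those fits, among them without control replicate 2 (0.0149), without control replicate 3 (0.0467) and with voom on recovered reads (0.0406). After the GC correction the list was not called, and its median log2 fold change was 0.05 (camera adjusted p = 0.243). Stromal progenitor genes held 4 rises and 2 falls among 26 (5 and 3 adjusted over the list alone; adjusted p = 0.623). Foxc1 rose from 57.9 ± 14.7 to 136 ± 15.8 FPKM, Kitl (stem cell factor) from 5.76 ± 1.06 to 13.2 ± 2.83, Twist1 from 25.5 ± 1.88 to 50.2 ± 9.35 and Ebf3 1.69-fold (log2 fold change 0.70, SE 0.12). None of 6 measured chondrocyte genes passed by limma over all genes, and 1 rose adjusted over the list alone (3 at an unadjusted p under 0.05, 1 called by voom; adjusted p = 0.201). Col2a1 was at 198 ± 28.8 and 312 ± 65.9 FPKM and Col11a2 at 1.03 ± 0.218 and 1.70 ± 0.417.

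In insulin and IGF signalling 6 of 39 genes rose and none fell (10 and 2 adjusted over the list alone), with no call for the list (adjusted p = 0.189). Besides Igf2, the IGF-binding Igfbp4 rose from 551 ± 80.8 to 1103 ± 18.6 FPKM (adjusted p = 0.00989), and Socs3, a feedback inhibitor of cytokine and insulin receptors, from 38.2 ± 1.34 to 57.6 ± 6.87. The receptors Insr (4.12 ± 0.357 and 3.69 ± 0.157 FPKM) and Igf1r (log2 fold change 0.02, SE 0.09) did not pass and were named after their values were seen. The list of bone-derived and metabolic secreted factors had 6 rises and 6 falls among 27 (11 and 6 adjusted over the list alone; camera adjusted p = 0.253, fry 0.00106), with Igf2, Bglap2 and Adipoq among the rises and Postn among the falls.

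Wnt genes were higher as a list (median log2 fold change 0.27, adjusted p = 0.00296, 9.28e-04 to 0.0147 over 22 alternative fits, and adjusted p = 0.504 with an estimated correlation), with 5 rises and 2 falls among 30 (13 and 3 adjusted over the list alone). The receptor Fzd1 rose from 49.3 ± 0.839 to 94.9 ± 9.48 FPKM (adjusted p = 0.00527), the secreted antagonist Sfrp1 from 43.1 ± 12.9 to 82.7 ± 5.72 and Wnt11 as above. Ccn4 (WISP1), a Wnt-induced matrix protein, fell from 90.7 ± 2.74 to 43.3 ± 3.23 (adjusted p = 0.00239). TGF-beta and BMP genes went both ways, with 6 rises and 4 falls among 40 (11 and 5 adjusted over the list alone; adjusted p = 0.657), and their median of 0.02 was -0.02 under quantile normalization, which moved the median of all genes to -0.034. Id4, a BMP-induced inhibitor of transcription factors, rose from 21.7 ± 4.01 to 65.8 ± 13.2 FPKM and Inhbb from 7.37 ± 0.862 to 19.2 ± 4.13, whereas Inhba fell from 49.0 ± 8.18 to 24.3 ± 3.30.

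Matrix genes were lower as a list (median log2 fold change -0.23, adjusted p = 0.00181, 5.80e-06 to 0.0221 over 22 alternative fits, and adjusted p = 0.523 with an estimated correlation), with 9 falls and 3 rises among 39 (12 and 3 adjusted over the list alone). Postn, Fbln2 (140 ± 27.5 to 77.0 ± 11.3 FPKM) and Vcan (5.66 ± 1.96 to 2.57 ± 0.254) fell, and Prelp, a leucine-rich proteoglycan, rose from 24.3 ± 1.44 to 44.2 ± 5.41. Among proteases and their inhibitors 5 of 23 fell and 1 rose (6 and 3 adjusted over the list alone; adjusted p = 0.189). The metalloproteinase Adamts12 fell from 37.1 ± 0.860 to 20.3 ± 1.24 FPKM (adjusted p = 0.00349) and Adamts4 from 10.8 ± 1.03 to 6.75 ± 0.652, while Mmp9, also a gene of osteoclasts and neutrophils, went from 0.486 ± 0.126 to 2.43 ± 1.18. The calls of Vcan and Mmp9 did not hold after the GC correction, with log2 fold changes of -0.86 and 1.15 before and -0.80 and 1.07 after.

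Markers of blood cells were present in both groups. The macrophage genes C1qb (367 ± 105 and 478 ± 71.6 FPKM), Cd68 (153 ± 45.6 and 219 ± 21.9) and Tyrobp (218 ± 32.1 and 277 ± 37.3), named after their values were seen, were among the abundant transcripts of controls and cKO. None of 27 macrophage and monocyte genes passed by limma over all genes or adjusted over the list alone (7 at an unadjusted p under 0.05, 1 called by voom), Spi1 being at 52.6 ± 11.9 and 84.7 ± 10.2 FPKM and Ctss having a log2 fold change of 0.45 (SE 0.17). The list as such was higher (median log2 fold change 0.22, adjusted p = 0.0363, 6.85e-04 to 0.542 over 22 alternative fits, and adjusted p = 0.732 with an estimated correlation), except without control replicate 3 (adjusted p = 0.542) and cKO replicate 3 (0.182). Granulocyte genes were higher as a list (median log2 fold change 1.21, adjusted p = 4.22e-04, 5.76e-07 to 0.00466 over 22 alternative fits, and adjusted p = 0.504 with an estimated correlation), and all 11 measured members had a positive log2 fold change. Of them 1 passed over all genes and 8 adjusted over the list alone. Retnlg rose from 0.188 ± 0.169 to 1.78 ± 0.695 FPKM, on 4, 0 and 3 reads in controls 2, 3 and 4 and 27, 15 and 24 in cKO 2, 3 and 4. Its control level lay under the filter of 0.5 FPKM, so it was tested only through its cKO level. Low genes that enter in this way favour rises among the measured members. S100a8, at 5.48 ± 3.97 and 35.8 ± 19.2 FPKM, and Lcn2, at 0.826 ± 0.666 and 5.28 ± 3.13, did not pass (adjusted p = 0.0574 and 0.0507; named after their values were seen). In control replicate 3, which stood apart, S100a8 was at 0.935 FPKM, against 8.29 and 7.21 in controls 2 and 4. Osteoclast genes held 2 rises and 1 fall among 9 (5 and 1 adjusted over the list alone; adjusted p = 0.114), with Atp6v0d2, a proton pump subunit, rising from 3.12 ± 0.710 to 7.83 ± 2.15 FPKM and the integrin Itgb3 falling from 10.2 ± 1.17 to 6.05 ± 0.570. Lymphocyte and erythroid lists had 4 measured members each, too few for the list test. By limma they had no call over all genes or adjusted over the list alone (3 and 0 at an unadjusted p under 0.05, none called by voom). Cd4 was at 0.552 ± 0.237 and 1.07 ± 0.145 FPKM and Ighm at 2.08 ± 1.13 and 3.85 ± 0.387. Gp1bb had a log2 fold change of 0.30 (SE 0.14) and Epor was at 1.49 ± 0.268 and 2.16 ± 0.738 FPKM.

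Endothelial and smooth muscle genes were lower as lists at the preset correlation, but not with an estimated one (adjusted p = 0.504 for both). Of 15 endothelial genes 2 fell and none rose (4 and 0 adjusted over the list alone), the vessel sialomucin Emcn from 3.16 ± 0.276 to 1.99 ± 0.283 FPKM and the transcription factor Erg from 4.13 ± 0.683 to 2.56 ± 0.358. The list was lower (median log2 fold change -0.21, adjusted p = 0.00431, 2.65e-05 to 0.0521 over 22 alternative fits), the highest value being without control replicate 2. Emcn and Erg lost their calls after the GC correction, with log2 fold changes of -0.48 and -0.52 before and -0.41 and -0.52 after. Of 15 smooth muscle and myofibroblast genes 14 had a negative log2 fold change and 1 passed (3 adjusted over the list alone), Synpo2, an actin-binding protein, from 8.09 ± 0.356 to 5.32 ± 0.131 FPKM. As a list they were lower (median log2 fold change -0.15, adjusted p = 0.00539, 4.42e-04 to 0.0410 over 22 alternative fits). Only 3 skeletal muscle and 3 neural genes were measured. No skeletal muscle gene passed by limma over all genes or adjusted over the list alone (1 at an unadjusted p under 0.05, 0 called by voom), with Mylpf at 0.697 ± 0.239 and 0.321 ± 0.0591 FPKM and Tnnt3 at 0.713 ± 0.0435 and 0.611 ± 0.165. The calcium-binding S100b of the neural list rose from 1.43 ± 0.0379 to 3.49 ± 0.587 FPKM, 1 of 3 over all genes and adjusted over the list alone.

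Antigen presentation genes accounted for the calls of the interferon list. H2-D1 rose from 238 ± 58.2 to 449 ± 14.2 FPKM, H2-K1 from 117 ± 21.2 to 208 ± 13.5, the peptide transporter Tap1 1.47-fold (log2 fold change 0.50, SE 0.10) and B2m, the light chain of class I molecules, from 508 ± 48.8 to 717 ± 88.3. H2-D1 and H2-K1 are close paralogs that can share reads. These 4 were the only calls among 29 members, over all genes and adjusted over the list alone, and Tap1 did not pass after the GC correction (log2 fold change 0.50 before, 0.40 after). B2m lay just inside the threshold (adjusted p = 0.0136 to 0.161 over 22 alternative fits) and lost its call in 15 of them. The list was higher (median log2 fold change 0.12, adjusted p = 0.0363, 4.76e-04 to 0.748 over 22 alternative fits, and adjusted p = 0.732 with an estimated correlation), but not without control replicate 3 (adjusted p = 0.0809), control replicate 4 (0.14) or cKO replicate 2 (0.748), nor with no filter on low genes (0.0505). Complement genes were higher as a list (median log2 fold change 0.27, adjusted p = 0.0209, 0.00300 to 0.0529 over 22 alternative fits, and adjusted p = 0.504 with an estimated correlation), with 1 rise among 11 (5 rises and 1 fall adjusted over the list alone). That rise was in properdin, Cfp, an X-linked gene that went from 58.1 ± 11.5 to 96.3 ± 12.5 FPKM and did not pass after the GC correction (log2 fold change 0.73 before, 0.61 after). The highest p of the list came from leaving out the genes on X and Y. Inflammatory and NF-kB genes had 2 rises and 2 falls among 22 (4 and 2 adjusted over the list alone; adjusted p = 0.772), with a median log2 fold change of 0.08 and a mean of -0.09. The chemokine Ccl2 fell from 7.11 ± 0.833 to 3.85 ± 0.651 FPKM, like Ccl7, and the NF-kB subunits Relb (8.14 ± 0.434 to 10.7 ± 0.562) and Nfkb2 (23.6 ± 0.208 to 29.4 ± 1.18) rose. After the GC correction neither of the pair passed, with log2 fold changes of 0.36 and 0.31 before and 0.23 and 0.09 after. Immediate early genes had 2 rises among 24, Klf2 and Jund (53.1 ± 5.31 to 85.4 ± 9.49 FPKM), over all genes and adjusted over the list alone, with no call for the list (adjusted p = 0.848). Without control replicate 3 the list was lower (adjusted p = 3.29e-08), and Jund did not pass after the GC correction (log2 fold change 0.67 before, 0.21 after).

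Lipid synthesis genes were lower as a list (median log2 fold change -0.20, adjusted p = 7.53e-04, 4.39e-05 to 0.0119 over 22 alternative fits, and adjusted p = 0.516 with an estimated correlation), with 4 falls and no rise among 31 (9 and 2 adjusted over the list alone). The fatty acid desaturase Scd2 fell from 56.5 ± 5.89 to 38.3 ± 0.675 FPKM, its relative Scd1 from 12.2 ± 0.853 to 9.08 ± 0.591 and Acaca, acetyl-CoA carboxylase, from 2.82 ± 0.123 to 2.16 ± 0.0396. Acaca did not pass after the GC correction (log2 fold change -0.28 before, -0.25 after). Genes of the unfolded protein response were lower too (median log2 fold change -0.16, adjusted p = 7.53e-04, 5.65e-05 to 0.00509 over 22 alternative fits, and adjusted p = 0.504 with an estimated correlation), with 2 falls and 1 rise among 26 (6 and 2 adjusted over the list alone). Asparagine synthetase, Asns, fell from 49.0 ± 6.61 to 31.7 ± 3.36 FPKM and the chaperone Hsp90b1 from 107 ± 10.6 to 82.1 ± 2.79, while Sdf2l1 rose from 37.9 ± 7.35 to 56.7 ± 2.82. After the GC correction Hsp90b1 and Sdf2l1 did not pass, with log2 fold changes of -0.38 and 0.58 before and -0.31 and 0.46 after. Cytosolic ribosomal protein genes were lower as a list (median log2 fold change -0.18, adjusted p = 3.38e-08, 2.53e-12 to 0.00123 over 22 alternative fits, and adjusted p = 0.522 with an estimated correlation). Of these 55 genes 49 had a negative log2 fold change and 5 fell (7 adjusted over the list alone), among them Rps7 (427 ± 25.5 to 320 ± 24.7 FPKM), Rps23 (474 ± 45.5 to 362 ± 11.3), Rps20 (104 ± 6.94 to 82.9 ± 3.36) and Rpl5 (88.3 ± 4.37 to 72.0 ± 2.71). Pseudogene copies can share their reads, and of these 4 Rps7 alone passed after the GC correction. The log2 fold changes of Rps23, Rps20 and Rpl5 were -0.38, -0.32 and -0.29 before and -0.33, -0.25 and -0.22 after. Grouped by symbol root, a choice made after the results were seen, neither ribosomal family was called. Of 67 Rps genes 39 were negative (camera adjusted p = 0.181), and of 84 Rpl genes 45 (0.533). Such groups can take in pseudogenes and other genes with that root.

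Hypoxia targets were lower as a list (median log2 fold change -0.16, adjusted p = 0.0363, 0.00526 to 0.144 over 22 alternative fits, and adjusted p = 0.504 with an estimated correlation), with 3 falls and 1 rise among 19 (7 and 1 adjusted over the list alone). The mTORC1 inhibitor Ddit4 fell from 29.7 ± 5.05 to 14.8 ± 1.33 FPKM, the collagen cross-linker Loxl2 with a log2 fold change of -0.64 (SE 0.08) and Hif1a from 27.6 ± 1.67 to 21.0 ± 1.58, while the oxygen sensor Egln1 rose from 18.1 ± 0.970 to 29.0 ± 3.25. The list did not pass in 8 of the 22 fits, among them those without control replicate 2 (adjusted p = 0.144), without cKO replicate 2 (0.0964) and after the GC correction (0.0765), under which Hif1a also lost its call (log2 fold change -0.38 before, -0.31 after). Glycolysis genes had 1 fall among 24, over all genes and adjusted over the list alone, in Pdk4, a brake on pyruvate oxidation (27.0 ± 3.44 to 17.4 ± 1.26 FPKM). The list was not called (adjusted p = 0.119), but was lower in 5 of 22 alternative fits, among them without control replicate 3 (0.00282), without cKO replicate 4 (0.0316) and after the GC correction (0.0128). Nuclear genes of oxidative phosphorylation had 1 rise among 44, over all genes and adjusted over the list alone, in Atp5d (69.7 ± 4.31 to 92.4 ± 3.93 FPKM), which did not pass after the GC correction (log2 fold change 0.40 before, 0.19 after). The list was not called (adjusted p = 0.947, median log2 fold change -0.03, mean 0.00). None of the 15 mitochondrially encoded genes passed by limma over all genes or adjusted over the list alone (2 at an unadjusted p under 0.05, 0 called by voom; list adjusted p = 0.246, and 0.0303 without cKO replicate 3), with mt-Nd5 at 521 ± 5.32 and 438 ± 39.2 FPKM and mt-Cytb at 1458 ± 72.8 and 1247 ± 67.5. NRF2 target genes had 2 rises among 24 (4 rises and 1 fall adjusted over the list alone; adjusted p = 0.128, and 0.0379 with array weights), the glutathione transferase Gsta3 (1.46 ± 0.197 to 2.66 ± 0.293 FPKM) and sulfiredoxin, Srxn1 (36.6 ± 1.75 to 49.1 ± 3.19).

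Proliferation genes held 1 rise among 38 over all genes, in E2f1 (11.6 ± 1.75 to 17.2 ± 0.775 FPKM), which did not pass after the GC correction (log2 fold change 0.54 before, 0.36 after), and none adjusted over the list alone. The list was not called (adjusted p = 0.148), but was lower without control replicate 3 (0.0229) and without cKO replicate 2 (0.00443). Senescence and p53 target genes had 2 rises and 2 falls among 22, over all genes and adjusted over the list alone, and no call for the list (adjusted p = 0.119; lower in 3 of 22 alternative fits, with 0.0336 after the GC correction). The proapoptotic Bbc3 (21.8 ± 3.69 to 41.0 ± 5.66 FPKM) and Phlda3 (234 ± 42.9 to 358 ± 26.3) rose, and proapoptotic Pmaip1 (17.6 ± 2.73 to 8.44 ± 1.12) and Mdm2, which degrades p53 (22.0 ± 1.66 to 16.4 ± 1.71), fell. Of these 4, Pmaip1 alone passed after the GC correction. The log2 fold changes of Bbc3, Phlda3 and Mdm2 were 0.88, 0.62 and -0.40 before and 0.48, 0.30 and -0.35 after.

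The higher genes were richer in G and C than the rest. Their transcripts had a median GC content of 57.1%, against 49.8% for all tested genes and 47.3% for the lower genes. In the tenth of genes with the most GC 21.4% were higher and 0.5% lower in cKO, and in the tenth with the least 1.4% were higher and 2.4% lower. The trend also differed between libraries of a group. From the tenth with the least to that with the most GC, the median deviation from the 6-library mean changed by -0.06, -0.23 and -0.19 on the log2 scale in controls 2, 3 and 4, and by 0.07, 0.11 and 0.30 in cKO 2, 3 and 4. After each library was corrected for its trend 361 of the 672 rises and 242 of the 342 falls kept their calls.

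**Figure D3:**
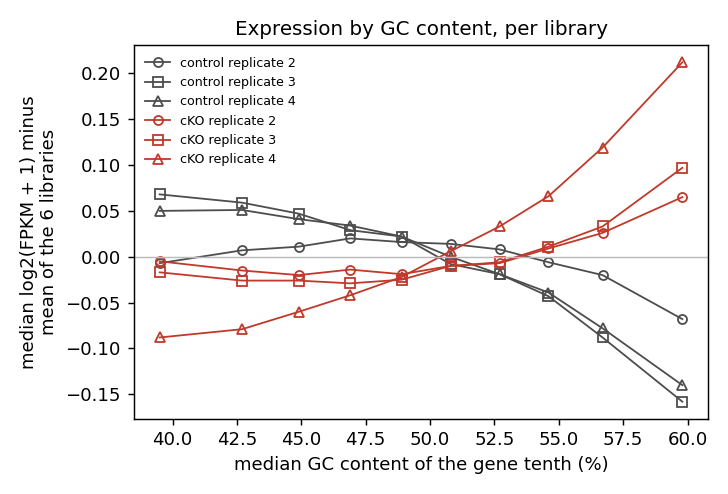
Median deviation of log2(FPKM + 1) from the mean of the 6 libraries (vertical axis) in 10 equal bins of the tested genes ordered by GC content (horizontal axis, %), with a line for each library. In the tenth with the most GC the cKO libraries lie above 0 and the controls below, cKO replicate 4 being the farthest up and control replicate 3 the farthest down.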

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

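The voom, GC-corrected, X and Y and multi-exon tests were chosen only after the results were seen. The 93 genes taken by the naming rule kept their direction in all refits, and over 2026 results 1505 stayed past the threshold and 521 did not. Their values did not overlap between the groups. Most refits, such as other pseudocounts, variance priors or weights or 1 library left out, therefore could not turn a direction. With no filter on low genes 327 were higher and 184 lower; quantile normalization gave 560 lower, array weights 1765 and 1378, voom 541 lower and the GC correction 388 higher, and the cause was not tested. An adjusted p under 0.1 gave 1346 and 891, and a fold of at least 2 gave 69 and 21. Leaving out 1 library gave 45 to 626 genes higher and 26 to 374 lower, and log2 fold changes of -0.55 to -0.48 for Ift140. With the replicate number as a block 42 genes were higher and 22 lower and Ift140 had -0.51 (limma adjusted p = 0.0633, 0.00294 to 0.0724 over its alternatives). With the GC correction and the block it was 1, 2 and -0.52. Same-numbered libraries did not deviate together (correlations of -0.04, -0.05 and 0.03) and 2 of 6 correlated best with their own number, so the numbers were not taken as pairs. Of the lists none was called with an estimated correlation (0 of 34, by camera, 0 at an unadjusted p under 0.05) and 4 by fry. Over 744 list results 20 lost and 20 gained a call. The immediate early list turned its direction and was lower with array weights (adjusted p = 0.0493) and in the fits without 1 library its adjusted p was 3.29e-08 to 0.914, the lowest without control replicate 3; the cause was not tested. Another 14 results over 6 lists changed direction with no call in either fit and are counted as kept. DESeq2 was not run on the recovered reads, which were tested with voom. The smallest simulated changes were mostly missed by the test on log2 FPKM (8% recovered, 32% by voom on the same reads), so the choice of test sets part of the limit and a gene without a call is not shown to be unchanged.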

Other observations

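The tests of the sex of the groups, of swapped libraries, of sex against genotype, of GC content, of 1 deciding library, of the stromal share and of gene families and classes were chosen only after the results were seen. Of 142 families of genes that share a symbol root, translation initiation factors (Eif) were lower, with 42 of 55 members at a negative log2 fold change (median -0.11, camera adjusted p = 0.0130, and 0.0203 without the members on X and Y). The Sec family of protein translocation and vesicle genes had 20 of 24 members negative (median -0.12, adjusted p = 0.0380), and C-type lectins (Clec), many of them receptors of myeloid cells, had 14 of 15 positive (median 0.37, adjusted p = 0.0380). With an estimated correlation the adjusted p was 0.986 for each of the 3 families, and after the GC correction the Sec family was not called (median -0.08, adjusted p = 0.0727). Of 251 protein-coding genes without introns 21.1% were higher, against 5.0% of 11499 with introns, and their median log2 fold change of 0.21 was 0.13 after the GC correction. Within 20 Mb of Ift140 37 of 407 tested genes were called (9.1%, 2-sided Fisher's exact p = 0.254).

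Xist and the Y-linked genes separated the groups. The cKO libraries held 1 read of the 4 Y-linked genes in all, and 0 libraries lay on the other group's side for Ift140, which argues against libraries swapped between the groups. A candidate explanation is that the control cultures came from male and the cKO cultures from female mice. Whether sex or genotype changed the autosomal genes cannot be told apart, because neither group shows both expression patterns. Of the called genes 3.7% lay on X or Y, as did 3.3% of the tested genes.

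More genes were higher than lower in cKO, and the higher ones were rich in GC. The GC trend that the correction removed does not account for all the rises, as 53.7% of them kept their call after it. The rises kept had a median GC content of 53.1%, against 49.8% for all tested genes. Bias that the correction misses is therefore not excluded. More genomic DNA in the cKO libraries stays open. The summed FPKM of 33 olfactory receptor genes was 1.5 on average in cKO, and 1.66 on average and up to 1.75 in controls. A cKO mean no higher than the highest control was set before the test as a sign against this explanation. However, the gap lay within 2 standard errors (SE 0.168), a margin that rule did not hold, and rested on 23 to 60 reads per library. The 487 processed pseudogenes had a median log2 fold change of 0.20 (0.18 after the GC correction). For the 311 rises lost on correction the median log2 fold change went from 0.47 (quartiles 0.38 and 0.60) to 0.25 (0.15 and 0.38) while the median SE went from 0.09 to 0.08, so that most of these folds shrank and the errors did not grow in the median. The log2 fold change stayed at 80 percent or more of its value in 34 of the 311, among them Frat1, Bglap and Mmp9, so a smaller fold does not account for each lost call. For the lost rises, bias and a change of GC-rich genes in the cells cannot be told apart, because the trend differs between the groups and a correction removes either.

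Granulocyte genes were higher as a list in cKO (adjusted p = 0.504 with an estimated correlation), with 1 of 11 members past the threshold over all genes and Lcn2 not past it (limma adjusted p = 0.0507). Carry-over of granulocytes into the cKO cultures may account for this: the summed reads of 15 other granulocyte genes, listed before the test, were 4.09 times higher (9.59 ± 3.77 and 39.2 ± 23.5 RPM, SD, n = 3), each cKO library above each control, and 2.72 times higher without cKO replicate 2. S100a8, among the most abundant granulocyte transcripts, was at 5.48 ± 3.97 and 35.8 ± 19.2 FPKM. Without any 1 library the median log2 fold change of the list stayed at 1.01 or more, which argues against 1 library as the cause. A lower share of stromal cells as the cause of the whole rise would raise the macrophage list by about as much. The mean log2 fold change of that list was 0.21 (SE 0.20) against 1.46. It lay under 50 percent of the granulocyte value by 0.52 ± 0.21 (SE, n = 3). This gap passed the margin set for it, but that margin was chosen after the results were seen. With 3 libraries per group the gap is too small against its SE to decide the question. A stromal share that changed by less, and so gave part of the rise, is not excluded either. An effect of the genotype or sex on granulocytes was not tested.

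The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. For genes 1 split, the real one, gave as many calls (1014, highest other 1), and for lists likewise 1 (14, highest other 13). Every other split puts libraries of both genotypes on each side, so a difference between the genotypes adds to its spread and holds its gene calls down. The gap in gene calls is therefore no support.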
